A study of Mus musculus with 6 samples.

How the data were processed

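Quadriceps muscle of 20-week-old male C57BL/6 mice was profiled by RNA sequencing in 2 groups of 3 libraries each. MERKO mice lack the estrogen receptor ERα (gene Esr1) in muscle, and wild-type mice served as control. Per the labels' protocols, RNA was isolated with Trizol and libraries were made with the Illumina TruSeq RNA kit. The authors deposited a table of raw read counts per gene, with 48795 genes named by versioned Ensembl identifier and 1 column per library. The submitters' processing notes name STAR 2.5.2b, HTSeq 0.9.1 and DESeq with the builds mm10 and GRCm38. The role of each tool, the annotation release, the strand setting and the treatment of reads with several placements are not given in the sources used here. For that reason, counts of overlapping or antisense genes and of near-identical copies are uncertain in what follows. The whole-number columns sum to different totals, and every column belonged to a labelled sample. No entry of the table stood for unassigned reads. The labels do not say more about the replicates than that 3 libraries were made per genotype, so p-values measure the spread between these libraries.

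Groups and replicate numbers were taken from the sample titles. Gene symbols were matched to 48349 identifiers, and 446 had no symbol. Coordinates, biotypes and exon lengths come from the GENCODE M21 annotation of GRCm38, matched on identifiers without their version. The test, the gene lists, the rule for naming genes and most alternative settings were fixed before the data were examined.

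MERKO and control were compared with the edgeR 4.0.16 quasi-likelihood test in R 4.3.3, with genotype as the sole term. Genes were kept by filterByExpr, which left 13628, and libraries were scaled by TMM factors. Adjusted p-values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05. Fold changes are log2 of MERKO minus control with their standard errors and 95% confidence intervals. Per-library values are CPM, counts scaled to a common library size, with TMM factors, given as mean ± SD with n = 3 per group. The biological coefficient of variation was 18.6%, and the prior degrees of freedom were 4.19.

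The 41 gene lists covered mitochondrial function, metabolism, stress responses, muscle fibre types and markers of other cell types. They were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and the preset inter-gene correlation of 0.01. Camera compares a list with all other genes, and its p-values were adjusted over the 41 lists. Camera with a correlation estimated per list, and fry, were run as alternatives. A list score is the mean log2 CPM of its members in a library, relative to the mean of the 6 libraries. Scores were compared with exact two-sided permutation tests, for which 3 against 3 libraries allow no p below 0.1.

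Named genes followed 4 rules. The first took Esr1, Esr2, Gper1 and Esrra. The second took up to 12 genes with the largest fold change per direction that passed the threshold, had an average log2 CPM of at least 0 and did not overlap between groups, without predicted genes named Gm or Rik and genes without a symbol. Since fewer than 10 passed, the 10 genes with the lowest p and that expression level are given as values instead. The third allowed up to 4 lowest-p members of each list that was called or held a passing gene, of which 2 are given, a number chosen after the data were seen. The fourth took the 3 lowest-p members of the lists for mitochondrial fusion and fission, mitochondrial DNA maintenance and transcription, regulators of mitochondrial biogenesis, and insulin signalling and glucose transport.

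The code was tested on simulated data in which 200 genes of this comparison were changed per simulation, with 5 simulations and 13505 genes tested. It recovered 0.896% of genes changed 1.5-fold, 17.6% of those changed 2-fold and 78.5% of those changed 4-fold. False calls made up 7.69% of calls. A list shifted by 0.5 on the log2 scale was found in 5 of 5 simulations, with simulated genes varying independently of each other. With this test, depth and group size, most simulated 2-fold changes therefore stayed below the threshold. The share of each in this limit was not tested.

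Alternatives were DESeq2 1.42.0, limma-voom, RLE scaling, no composition factor, no filter, a filter of at least 1 CPM in at least 3 libraries, replicate number as a block, removal of genes of mitochondrial DNA, a threshold of 0.1, a robust prior and leaving out each library in turn. Further alternatives, chosen after the data were seen, are named in the closing section. Counts of reads without molecular identifiers are not counts of independent molecules, so intervals on shares of counts cover counting error only. The 2 libraries of any pair within a group differed by far more than sampling noise, with a chi-square per degree of freedom of at least 116.9 over genes. It was lower for some pairs across groups, at 26.22 for MERKO 2 and control 2. It includes the rRNA gene model CT010467.1, whose share ran from 0.0433% to 32.4%, so it cannot show separate animals. All 6 libraries were counted as separate samples because the labels list them so.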

Results

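The data hold read counts per gene in quadriceps muscle of male MERKO mice, in which the estrogen receptor gene Esr1 was targeted in muscle, and of wild-type control mice, with 3 libraries per group. The totals were 26596608, 15755947 and 22185479 counts in MERKO 1 to 3, and 21809041, 14935532 and 44282448 in control 1 to 3. Correlations of log2 CPM across genes lay between 0.959 and 0.982 for all pairs of libraries, where genes are not independent replicates.

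The make-up of the libraries differed within both groups. The rRNA gene model CT010467.1 took 6.19%, 32.4% and 19.2% of counts in MERKO 1 to 3 and 11.1% and 27.7% in control 1 and 2. In control 3 its share was 0.0433% (95% exact binomial interval 0.0427% to 0.0439%). Genes of mitochondrial DNA took 4.90% of counts in MERKO 2, 6.68% in control 2 and between 10.4% and 11.0% in the other libraries. Genes of slow-twitch fibres were high in 1 library of each group. Myh7, the slow myosin heavy chain, stood at 160 CPM in MERKO 1 and 185 CPM in control 1, and between 1.77 and 8.07 CPM in the other 4 libraries.

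**Figure D1:**
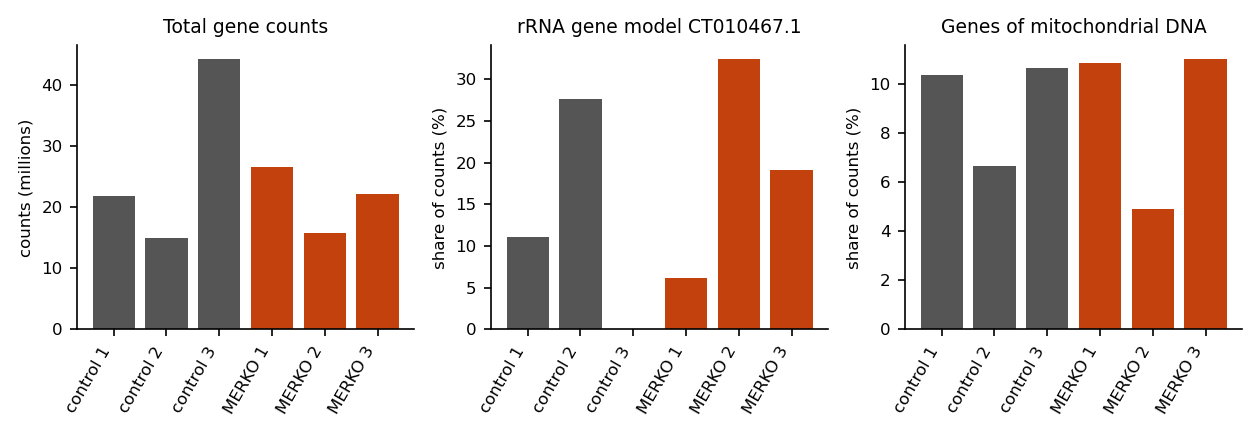
Total counts, share of counts in the rRNA gene model CT010467.1 and share in genes of mitochondrial DNA, both in percent, for each of 3 control (grey) and 3 MERKO (orange) libraries. Control 3 has the highest total, 44282448 counts, and an rRNA share of 0.0433%, too small to show as a bar.

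The first question was whether Esr1 transcripts were reduced in the muscle of the knockout animals. Esr1 (ENSMUSG00000019768.16, GRCm38 chromosome 10, 4611593 to 5005614, plus strand) stood at 7.88 ± 1.39 CPM in MERKO and 30.1 ± 4.59 CPM in control (SD, n = 3 each). Its counts were 222, 112 and 155 in MERKO 1 to 3, and 597, 432 and 1694 in control 1 to 3, and every MERKO library lay below every control library in CPM. Esr1 fell by 1.95 on the log2 scale (SE 0.16, 95% interval -2.33 to -1.57, adjusted p = 0.0262, edgeR quasi-likelihood test), leaving 25.9% of the control level (19.9% to 33.7%). The count sums all exons in whole muscle, which also holds vessels, nerve and connective tissue, so the remaining reads cannot be apportioned between cell types or to a truncated transcript. The fold change lay between -2.08 and -1.84 when any library was left out, but the adjusted p was 0.102 without MERKO 1, 0.0576 without MERKO 2, 0.109 without control 2, 0.0632 without control 3 and 0.242 without MERKO 2 and control 2 together, in a range from 8.6e-21 to 0.242 over all alternatives.

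Transcripts of 2 other receptors that respond to estrogen and of the related receptor Esrra were examined next. Esr2, which encodes ERβ, had between 1 and 5 counts per library and was not tested. Gper1, a membrane receptor that responds to estrogen, stood at 1.397 ± 0.62 CPM in MERKO and 1.74 ± 0.92 CPM in control (log2 fold change -0.25, SE 0.46, adjusted p = 0.916, edgeR). Esrra, an orphan nuclear receptor that does not bind estrogen and drives mitochondrial genes, stood at 66.3 ± 15.1 and 59.1 ± 16.7 CPM (log2 fold change 0.17, SE 0.22, adjusted p = 0.872). Of the 20 measured members of the list of estrogen receptors and reported estrogen targets, 1 passed over all genes and 3 passed when adjusted over the list alone, with 11 members higher and 9 lower. Next to Esr1, the member with the lowest p was Cited2, a transcriptional co-regulator, at 5.70 ± 0.55 CPM in MERKO and 8.68 ± 1.43 CPM in control (log2 fold change -0.62, SE 0.16, adjusted p = 0.654).

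The comparison over all genes asked what else differed between MERKO and control quadriceps. Esr1 was the 1 gene of 13628 that passed the threshold in the edgeR test, with 0 genes higher and 1 lower in MERKO. The next lowest adjusted p was 0.542. At an unadjusted p under 0.05 there were 960 genes, 505 higher and 455 lower, where 681 would be expected by chance and other splits of the 6 libraries gave up to 1475. The groups did not overlap in 1809 genes, or 13.3%, against 10% by chance. DESeq2 called 23 genes, 13 higher and 10 lower, and limma-voom called 1, with Esr1 in each set. The count was 0 without MERKO 1 or without MERKO 2, 11 without MERKO 3, 2 without control 1 (Esr1 and Nmrk2), 1 without control 2 (Gm1821), 2 without control 3 (Mettl21e and Alb) and 7 without MERKO 1 and control 1 together. These names outside the naming rule were chosen after their values were seen.

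Among the 10 genes with the lowest p, those below Esr1 are given as values, since none had an adjusted p under 0.542 in the edgeR test. Inmt, an indolethylamine N-methyltransferase, stood at 15.3 ± 3.17 CPM in MERKO and 37.6 ± 7.43 CPM in control (log2 fold change -1.29, SE 0.19). Fkbp5, a co-chaperone of the glucocorticoid receptor, stood at 55.4 ± 13.1 and 105 ± 7.64 CPM (-0.92, SE 0.17). A gene without a symbol, ENSMUSG00000094114.1, stood at 8.75 ± 0.87 and 16.7 ± 1.80 CPM (-0.92, SE 0.13). Ankrd1, an ankyrin repeat protein of the sarcomere, was at 9.85 ± 2.55 CPM in MERKO and 3.15 ± 0.91 CPM in control (1.62, SE 0.26). Mustn1, a nuclear protein of muscle and skeleton, was at 23.4 ± 2.13 and 11.7 ± 2.504 CPM (0.99, SE 0.16), and the kinase gene Sbk2 at 27.2 ± 2.88 and 12.4 ± 3.40 CPM (1.14, SE 0.19). Aldh1l2, a mitochondrial enzyme of folate metabolism, was at 5.52 ± 0.55 and 2.87 ± 0.34 CPM (0.94, SE 0.17), and the fibrillar collagen gene Col24a1 at 7.05 ± 1.93 and 2.88 ± 0.45 CPM (1.25, SE 0.23). Hspa1b, an inducible heat shock protein, was at 2.00 ± 0.24 and 0.55 ± 0.14 CPM (1.79, SE 0.29), with reads that could be shared with its near-identical copy Hspa1a. In each of these 9 genes all MERKO libraries lay on 1 side of all control libraries. DESeq2, run without the filterByExpr step and with its own scaling, called 8 of the 9, all but Aldh1l2. Its adjusted p-values ran from 1.43e-06 for Inmt to 0.032 for Hspa1b. DESeq2 was not run on the simulated data or on other splits of the libraries, so its share of false calls is unknown. Of the list members named in what follows, it called Ppp1r3c (adjusted p = 0.000643), Kera (0.0343) and Hspg2 (0.0364).

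**Figure D2:**
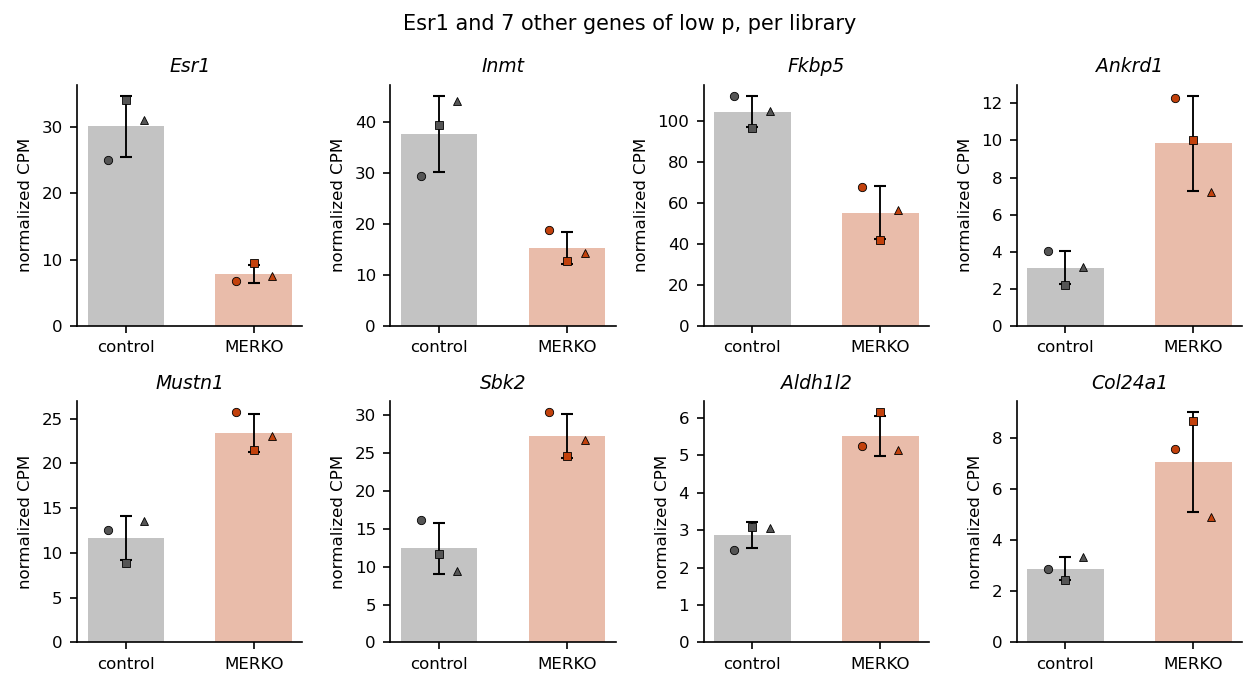
Normalized CPM of Esr1 and 7 other genes of low p in control (grey) and MERKO (orange) quadriceps. Bars are means, error bars the SD of 3 libraries, and circles, squares and triangles libraries 1, 2 and 3. The MERKO libraries lie below the control libraries for Esr1, Inmt and Fkbp5 and above them for the other 5 genes. Esr1 passed the edgeR test, and DESeq2 called all 8 but Aldh1l2.

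The series title names mitochondrial dynamics and metabolic homeostasis, and the lists for these functions were examined next. Of 28 measured genes of mitochondrial fusion and fission, 17 were higher, 11 lower and 0 passed, also when adjusted over the list alone (median log2 fold change 0.01, camera adjusted p = 0.949). Inf2, a formin that acts at sites of fission, was at 4.68 ± 0.52 CPM in MERKO and 3.30 ± 0.31 CPM in control (log2 fold change 0.50, 95% interval 0.12 to 0.87). Yme1l1, an inner-membrane protease, had a log2 fold change of -0.18 (-0.38 to 0.01), and Mfn1, a fusion GTPase of the outer membrane, of 0.34 (-0.13 to 0.81). The lists for mitochondrial DNA maintenance and transcription (27 members, adjusted p = 0.792) and for regulators of mitochondrial biogenesis (26 members, adjusted p = 0.524) held no passing gene either. In these lists the lowest p belonged to Primpol (log2 fold change 0.39, -0.13 to 0.91), Ssbp1 (-0.17, -0.43 to 0.09) and Mterf1a (0.64, -0.35 to 1.62), and to the co-activator gene Ppargc1b (0.55, -0.11 to 1.21), Gabpb1 (0.23, -0.11 to 0.57) and Esrrb (1.18, -1.04 to 3.39). Without MERKO 1 the log2 fold change was 0.15 for Mfn1, 0.36 for Mterf1a, 0.24 for Ppargc1b and -0.31 for Esrrb. Without control 1 it was 0.54 for Mfn1, 0.26 for Primpol and 2.896 for Esrrb, without control 3 it was 1.263 for Mterf1a, without MERKO 2 it was -0.09 for Ssbp1, and without control 2 it was 0.149 for Gabpb1.

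The nuclear-encoded respiratory chain genes had 34 of 80 members higher and 46 lower in MERKO, with a median log2 fold change of -0.02 and a camera adjusted p of 0.457. The proteins encoded by mitochondrial DNA (11 members, adjusted p = 0.708) and the tricarboxylic acid cycle (34 members, adjusted p = 0.668) were not called. Of the mitochondrial DNA genes, mt-Co2, mt-Co3 and mt-Atp6 had 0.956 to 7.65 CPM, against at least 15560 CPM for mt-Co1. The rules by which reads were assigned are not known, so unchanged expression cannot be read from that list. Of the 44 members of insulin signalling and glucose transport, 21 were higher and 23 lower (adjusted p = 0.644). Their lowest p-values belonged to Eif4ebp1, a repressor of translation, at 25.0 ± 3.33 CPM in MERKO and 32.6 ± 2.29 CPM in control (log2 fold change -0.38, -0.65 to -0.11), to Pik3r1, the regulatory subunit of PI3-kinase (-0.33, -0.65 to -0.01, and -0.21 without MERKO 2), and to Rptor, a component of mTORC1 (0.30, -0.00287 to 0.593). None passed over all genes or when adjusted over the list alone (edgeR). The edgeR test did not detect differences of these sizes, which does not show that they are absent. The genes were picked for low p, and their intervals are not adjusted for that choice.

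**Figure D3:**
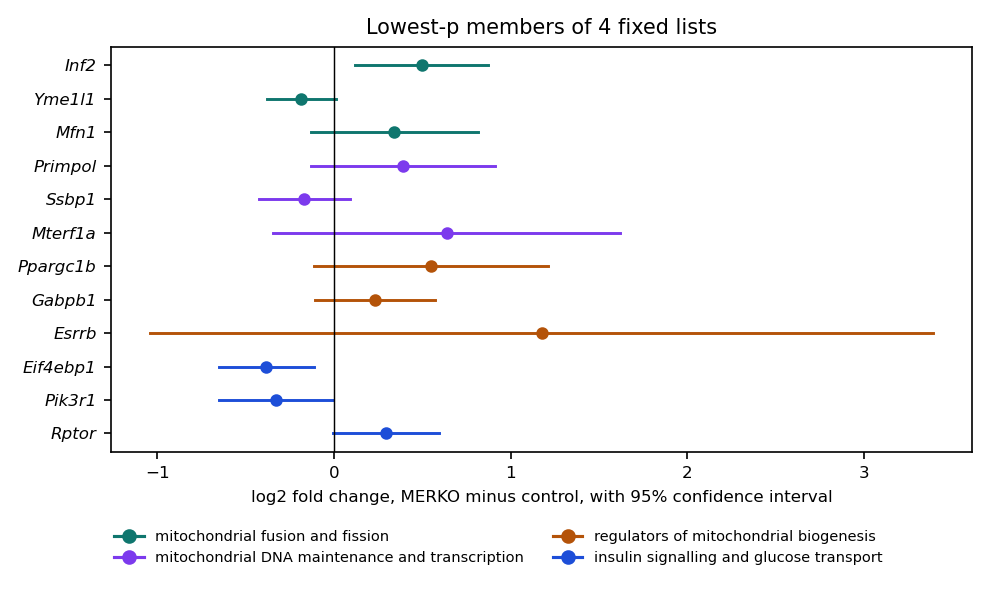
Log2 fold change of MERKO minus control with its 95% confidence interval for the 3 lowest-p members of 4 lists, coloured by list. The largest value, 1.18 for Esrrb, has an interval from -1.04 to 3.39, and no gene shown passed the test.

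Camera with its preset correlation called 14 of the 41 lists, 5 higher and 9 lower in MERKO. With a correlation estimated for each list 0 were called, and the smallest adjusted p was 0.747. Fry also called 0 in its directional test. In its mixed test, which asks for change in either direction, the list of estrogen receptors and reported targets, of which Esr1 is a member, had an adjusted p of 0.00413. The p-values with the preset correlation hold only if the members of a list vary nearly independently between libraries.

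All 76 measured cytosolic ribosomal protein genes were lower in MERKO, with a median log2 fold change of -0.24 (camera adjusted p = 9.26e-19, and adjusted p = 0.747 with an estimated correlation). Rpl34 stood at 43.1 ± 1.34 CPM in MERKO and 54.8 ± 5.39 CPM in control, and Rps20 at 95.7 ± 2.99 and 123 ± 13.1 CPM, with reads that could be shared with processed pseudogenes. Of 32 proteasome genes, 31 were lower (median -0.17, adjusted p = 6.42e-08, and 0.747 as the adjusted p with an estimated correlation). Psmc6 stood at 70.4 ± 3.56 and 84.6 ± 7.71 CPM and Psmb7 at 111 ± 3.52 and 132 ± 10.9 CPM. No member of these lists passed the edgeR test, over all genes or when adjusted over the list alone. Control 3, the deepest library with the lowest rRNA share, had the highest score of both lists, 0.29 for ribosomal proteins and 0.17 for the proteasome. Without control 3 the mean difference of the ribosomal list in log2 CPM was -0.136 in place of -0.224 (adjusted p = 8.53e-09 with the preset correlation). The mitochondrial ribosome list was also called lower (57 of 76 members, median -0.05, adjusted p = 0.0156, and 0.978 as the adjusted p with an estimated correlation), with Mrps14 at 20.3 ± 1.68 and 24.9 ± 1.73 CPM and Mrpl32 at 15.1 ± 1.39 and 18.5 ± 1.42 CPM. This call was lost without MERKO 2, MERKO 3 or control 1, with adjusted p-values of 0.374, 0.133 and 0.988 and mean differences of -0.00463, -0.0424 and 0.0162. The value of -0.0613 became -0.126 without MERKO 1 and -0.115 without control 2.

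Markers of tendon and fat differed in opposite directions. Of 14 tendon genes, 13 were higher in MERKO with a median log2 fold change of 2.08 (camera adjusted p = 2.43e-08, adjusted p = 0.747 with an estimated correlation, exact permutation p = 0.1, the smallest possible). Kera, the corneal and tendon proteoglycan keratocan, stood at 25.6, 14.5 and 4.09 CPM in MERKO 1 to 3 and at 2.27, 1.03 and 1.76 CPM in control 1 to 3. Comp, cartilage oligomeric matrix protein, stood at 32.7, 11.0 and 3.465 CPM in MERKO 1 to 3 and averaged 1.85 ± 0.96 CPM in control, with a log2 fold change of 3.07 that was 1.89 without MERKO 1. All 15 adipocyte genes were lower, with a median of -2.07 (adjusted p = 1.37e-08, adjusted p = 0.747 with an estimated correlation, exact permutation p = 0.1). The hormone genes Lep and Retn stood at 1.29 ± 0.70 and 1.27 ± 0.41 CPM in MERKO and at 9.42 ± 5.92 and 7.15 ± 6.50 CPM in control. Without control 2, which had the highest adipocyte score, the mean difference of this list in log2 CPM was -0.875 in place of -1.51 (adjusted p = 0.000135 with the preset correlation), and the log2 fold change of Retn was -1.56 in place of -2.50. No member of either list passed over all genes in the edgeR test, and 10 members of each passed when adjusted over the list alone. The neutrophil and mast cell list was lower in 5 of 6 members (median -0.48, adjusted p = 0.0139, and 0.747 as the adjusted p with an estimated correlation), with Mmp9 at 1.72 ± 0.22 and 3.62 ± 0.74 CPM and Mcpt4 at 2.76 ± 1.07 and 4.54 ± 1.55 CPM. Here 1 member passed when adjusted over the list alone. The call was lost without MERKO 2, control 2 or control 3, with adjusted p-values of 0.194, 0.126 and 0.0541 and mean differences of -0.195, -0.303 and -0.438 in place of -0.508.

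Most members of the extracellular matrix, nerve and heat shock lists were higher in MERKO. Collagens and other matrix genes were higher in 30 of 37 members (median 0.15, camera adjusted p = 0.000151, adjusted p = 0.747 with an estimated correlation), and 2 passed when adjusted over the list alone. Of the 3 most abundant members, Col1a2 was higher (log2 fold change 0.613), while Col3a1 (-0.081) and Col4a1 (-0.0962) were slightly lower. Hspg2, the basement membrane protein perlecan, stood at 157 ± 16.9 CPM in MERKO and 111 ± 4.22 CPM in control, and Bgn, the proteoglycan biglycan, at 12.1 ± 0.55 and 7.55 ± 1.36 CPM. The matrix scores were 0.33, 0.196 and 0.0259 in MERKO 1 to 3, where the tendon scores were 1.88, 0.976 and -0.128, and Fmod is in both lists. The matrix call was lost without MERKO 1 and control 1 together (adjusted p = 0.0697), where the mean difference was 0.221 in place of 0.368. Schwann cell and nerve genes were higher in 11 of 12 members (median 0.51, adjusted p = 0.00209, and 0.747 as the adjusted p with an estimated correlation), with Ngfr at 0.91 ± 0.20 and 0.30 ± 0.19 CPM and the myelin gene Pmp22 at 18.98 ± 4.40 and 14.3 ± 0.98 CPM. Without MERKO 1, which had the highest nerve score, the adjusted p was 0.142 and the mean difference 0.253 in place of 0.469. Heat shock genes were higher in 16 of 21 members (median 0.09, adjusted p = 0.00595, and 0.747 as the adjusted p with an estimated correlation). Beside Hspa1b, which passed when adjusted over the list alone, Hspb1 stood at 70.6 ± 7.88 and 51.5 ± 8.38 CPM. Without MERKO 3 the adjusted p was 0.0792, with the mean difference at 0.325 as before.

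**Figure D4:**
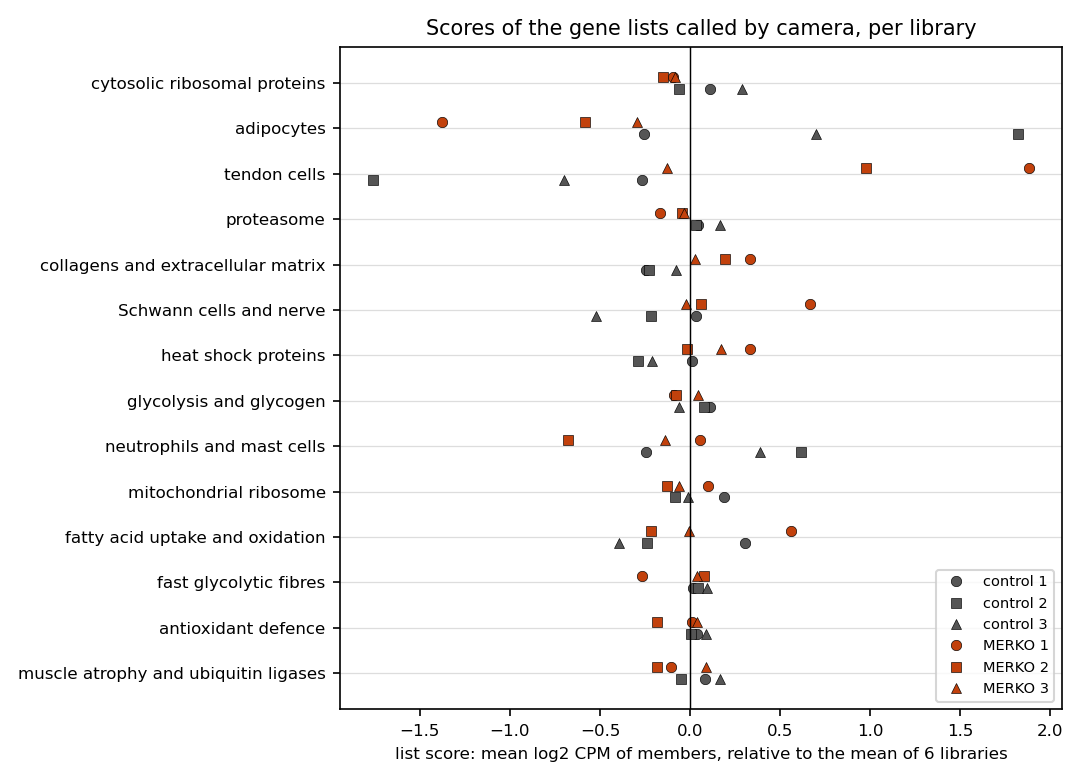
Score of each of the 14 lists called by camera with its preset correlation, as mean log2 CPM of the members relative to the mean of 6 libraries, for control (grey) and MERKO (orange) libraries 1 (circles), 2 (squares) and 3 (triangles). The groups are apart for tendon genes, where MERKO scores lie between -0.13 and 1.88 and control scores between -1.76 and -0.27, and overlap for glycolysis and fatty acid oxidation.

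The called lists of fuel use and fibre type had small differences in which the groups overlapped. Glycolysis and glycogen genes were lower in 26 of 39 members (median -0.16, camera adjusted p = 0.0139, adjusted p = 0.751 with an estimated correlation). Ppp1r3c, which targets protein phosphatase 1 to glycogen, stood at 539 ± 87.1 CPM in MERKO and 1273 ± 467 CPM in control (log2 fold change -1.24, SE 0.28), whereas Hk1, a hexokinase, was at 8.55 ± 2.42 and 6.05 ± 0.33 CPM. Fatty acid uptake and oxidation genes were higher in 36 of 41 members (median 0.22, adjusted p = 0.0157, and 0.978 as the adjusted p with an estimated correlation), with Cpt1a, the carnitine palmitoyltransferase of the outer membrane, at 15.2 ± 0.29 and 12.6 ± 1.39 CPM and Acacb at 316 ± 28.2 and 272 ± 41.5 CPM. The scores of this list were highest in MERKO 1 and control 1, the libraries with high slow-fibre genes, and without MERKO 1 the mean difference turned to -0.00239 (adjusted p = 0.88). The call was also lost without control 2 or control 3, with adjusted p-values of 0.175 and 0.555 and mean differences of 0.162 and 0.0785, and the value of 0.222 became 0.394 without MERKO 2 and 0.428 without control 1. Genes of fast glycolytic fibres were lower in 15 of 18 members (median -0.15, adjusted p = 0.0282, and 0.915 as the adjusted p with an estimated correlation), with Myl1 at 5022 ± 1165 and 6617 ± 1626 CPM and Myoz1 at 1250 ± 211 and 1480 ± 125 CPM. Without MERKO 1 the mean difference of this list turned to 0.00892 (adjusted p = 0.725), and without control 3 it was -0.0799 (adjusted p = 0.162). Without MERKO 2 the mean difference was -0.158 in place of -0.1. The glycolysis call was lost without MERKO 1, control 1 or control 2, with adjusted p-values of 0.155, 0.071 and 0.0564 and mean differences of -0.0586, -0.05 and -0.059 in place of -0.0827. Without control 3 it was -0.135.

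Antioxidant genes were lower in 31 of 42 members (median -0.11, camera adjusted p = 0.0283, adjusted p = 0.747 with an estimated correlation). The members with the lowest p went both ways, with Srxn1, sulfiredoxin, at 24.0 ± 2.81 CPM in MERKO and 18.1 ± 1.92 CPM in control and Gclm, a subunit of the enzyme for glutathione synthesis, at 9.56 ± 1.27 and 11.5 ± 0.87 CPM. Genes of muscle atrophy and ubiquitin ligases were lower in 23 of 30 members (median -0.13, adjusted p = 0.0412, and 0.747 as the adjusted p with an estimated correlation). Trim63, the ubiquitin ligase MuRF1, stood at 270 ± 85.8 and 471 ± 131 CPM, and the transcription factor gene Runx1 at 2.58 ± 0.24 and 1.60 ± 0.14 CPM. No gene of the fuel, fibre, antioxidant and atrophy lists passed when adjusted over the list alone. The antioxidant call was lost without MERKO 2, control 1 or control 3, with adjusted p-values of 0.293, 0.067 and 0.0988 and mean differences of -0.0146, -0.0939 and -0.0685 in place of -0.0901. The atrophy call was lost without MERKO 1, MERKO 2, control 1 or control 3, with adjusted p-values of 0.142, 0.122, 0.111 and 0.183 and mean differences of -0.114, -0.0674, -0.128 and -0.0833 in place of -0.133. Without MERKO 3 it was -0.207.

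Some of these calls also ended with other settings. Without a composition factor the adjusted p was 0.0733 for glycolysis, 0.0876 for the mitochondrial ribosome, 0.0942 for fast fibres and 0.0844 for antioxidant genes. In the same order, the mean differences were larger, at -0.209, -0.188, -0.227 and -0.215 in place of -0.0827, -0.0613, -0.1 and -0.0901. In that fit the log2 fold changes of all genes shifted by a median of -0.116. Without a filter the adjusted p was 0.285 for neutrophils and mast cells and 0.0695 for fatty acid oxidation, and with the stricter filter 0.053 for atrophy genes. The mean difference fell to -0.143 from -0.508 for neutrophils and mast cells. It was 0.218 in place of 0.222 for fatty acid oxidation and -0.127 in place of -0.133 for atrophy genes. With the length trend removed the adjusted p was 0.229 for the mitochondrial ribosome, 0.115 for fast fibres, 0.115 for antioxidant genes and 0.0527 for atrophy genes. Their mean differences were -0.0266, -0.0674, -0.0637 and -0.125. Without MERKO 1 and control 1 the adjusted p was 0.374 for glycolysis, 0.123 for the mitochondrial ribosome, 0.39 for fast fibres and 0.273 for atrophy genes. Here the mean differences were -0.0233, -0.0456, -0.00785 and -0.106. Without MERKO 2 and control 2 the adjusted p was 0.0659 for glycolysis, 0.728 for neutrophils and mast cells and 0.171 for antioxidant genes, with mean differences of -0.0394, -0.0245 and -0.0337.

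The remaining 27 lists were not called. Slow and oxidative fibre genes had a camera adjusted p of 0.708, with scores of 2.61 in MERKO 1 and 2.30 in control 1 against -1.61 to -0.66 in the other libraries. The genes of the neuromuscular junction and denervation came closest to the threshold (14 of 22 higher, adjusted p = 0.0928). Macrophage (adjusted p = 0.644), endothelial (0.731), fibroblast (0.868), lymphocyte (0.949) and erythrocyte (0.644) markers were not called. For lipid droplets and lipid synthesis (adjusted p = 0.609) the median log2 fold change was 0.04 and the mean -0.19, and median and mean also had opposite signs for the lists of estrogen targets, mitochondrial DNA maintenance, the circadian clock and lymphocytes.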

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

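The removal of rRNA-like models, the slow-fibre covariate, the 2 pairs of libraries left out together and the removal of a length trend were chosen after the results were seen; all other alternatives were set beforehand. Esr1 kept its direction in all 20 alternatives, with log2 fold changes from -2.08 to -1.84 and adjusted p from 8.6e-21 to 0.242, and passed in 15. It did not pass in 4 of the 6 fits that left out 1 library, whose fold changes span -2.08 to -1.84, nor without MERKO 2 and control 2 (-1.98), fits with fewer samples. The gene count stayed at 1 with limma-voom, RLE, the stricter filter, the robust prior, a threshold of 0.1, removal of mt- genes or rRNA-like models, and the length correction, and was Esr1 each time. DESeq2 called 23 (13 higher, 10 lower). Without a composition factor 93 genes passed (44 higher, 49 lower), and the median log2 fold change of all genes shifted by -0.12. Without a filter 140 passed (86 higher, 54 lower), with prior degrees of freedom of 23.5 in place of 4.19. The slow-fibre covariate gave 27 (16 higher, 11 lower), and leaving out MERKO 1 and control 1 gave 7 (2 higher, 5 lower). Without MERKO 2 and control 2, 1 gene was higher and 0 lower. Leaving out 1 library gave 0 to 11 genes, 0 to 8 higher and 0 to 3 lower. The causes of these differences in count were not tested. With the stricter filter 2 named genes were not tested.

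With the replicate number as a block, 51 genes passed (31 higher, 20 lower), Esr1, Atf3, Nmrk2, Thbs1, Scd1, Gpam and Gm15564 among them. The neutrophil and mast cell list lost its call (camera adjusted p = 0.0657), with its mean difference unchanged at -0.508. Same-numbered libraries deviated together with correlations of 0.448, 0.163 and 0.0612 across genes. Between-group pairs with different numbers had -0.314 to 0.184, the highest for MERKO 2 with control 3. MERKO 2 and control 2 also had the largest rRNA shares, 32.4% and 27.7%. The labels do not say what the numbers mean, so they were not taken to pair the samples. A preparation shared by same-numbered libraries is not excluded. Between 10 and 17 lists were called in every other fit with the preset correlation, against 14, and 0 with the estimated correlation or fry. No called list changed direction with another scaling. The values of the 14 lists stayed called in 195 of 266 cases, lost the call in 68 and turned sign in 3. When 1 library was left out, mean differences spanned -0.00239 to 0.428 for fatty acid oxidation, -0.158 to 0.00892 for fast fibres and -0.126 to 0.0162 for the mitochondrial ribosome. Of 1018 values of named genes other than Esr1, 5 turned sign and 56 passed the threshold. Leaving out 1 library moved the fold change of 20 of 52 named genes by over 1.5 times. Gper1 was at 0.0338 with limma-voom and between -0.732 and 0.299 with 1 library left out, Esrra between -0.0339 and 0.426, and Esrrb between -0.312 and 2.896; the causes were not tested. Esr2 had 1 to 5 counts per library, with 5 in control 3, the deepest, and 4 in MERKO 2. Low expression and low depth were not told apart.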

Other observations

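The genes named in the first 2 paragraphs and the tests on slow-fibre, tendon, adipocyte and Gm15564 genes were chosen only after their values were seen; the tests of genes near Esr1, of a glucocorticoid list and of other splits of the libraries were written down before their results. Among single genes, none of the following had an adjusted p under 0.631 in the edgeR test, while DESeq2 called Atf3 and Mettl21e. Atf3, a stress-induced transcription factor, stood at 3.61 ± 1.62 CPM in MERKO and 1.04 ± 0.38 CPM in control (SD, n = 3 each). Nmrk2, a muscle kinase of NAD synthesis, stood at 104 ± 10.5 and 43.7 ± 22.4 CPM (log2 fold change 1.255, SE 0.31), and the matrix protein gene Thbs1 at 27.6 ± 17.3 and 8.94 ± 3.27 CPM. Rcan1, an inhibitor of calcineurin, stood at 60.4 ± 5.92 and 38.8 ± 9.58 CPM (log2 fold change 0.64, SE 0.17, adjusted p = 0.654). Further core genes of mitochondrial dynamics and DNA copying had intervals that include 0, with log2 fold changes of 0.06 for Dnm1l (95% interval -0.19 to 0.30), 0.01 for Mfn2 (-0.28 to 0.31), 0.01 for Opa1 (-0.29 to 0.31) and 0.09 for Polg (-0.15 to 0.33).

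The list of lipid droplets and lipid synthesis had 19 members higher and 17 lower in MERKO and was not called (camera adjusted p = 0.609). In it, Scd1 stood at 102 ± 53.5 CPM in MERKO and 442 ± 349 CPM in control, Fasn at 33.2 ± 11.8 and 132 ± 131 CPM, and Acly at 16.0 ± 1.07 and 34.2 ± 25.4 CPM. Control 2 carried much of these control means, with 820.5, 282.7 and 63.45 CPM of Scd1, Fasn and Acly against 131.6, 40.79 and 18.32 CPM in control 1 and 374.1, 73.96 and 20.84 CPM in control 3. Adipocyte markers moved with them, with Adipoq at 4.83, 36.7 and 16.9 CPM in control 1 to 3 and at 2.16, 4.88 and 6.88 CPM in MERKO 1 to 3. In the same list, Gpam, the first enzyme of triglyceride synthesis, stood at 185 ± 33.6 and 127 ± 21.02 CPM, and the lipid droplet gene Plin2 at 24.0 ± 3.00 and 18.6 ± 1.14 CPM. Mettl21e, a lysine methyltransferase of muscle, was at 2.98, 2.02 and 3.32 CPM in MERKO 1 to 3 and at 32.5, 36.0 and 5.96 CPM in control 1 to 3 (log2 fold change -3.10, SE 0.62, adjusted p = 0.631, edgeR). Alb, an albumin gene, stood at 16.8 and 15.6 CPM in control 1 and 2 and at 1.16 CPM in control 3, against 1.68 to 2.52 CPM in MERKO. mt-Co2, mt-Co3 and mt-Atp6 had between 0.956 and 7.65 CPM in the 6 libraries while mt-Co1 had at least 15560 CPM. The cause was not tested, and these counts may not reflect transcript levels.

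Genes of the list of slow and oxidative fibres, in short slow-fibre genes, were high in MERKO 1 and control 1. All 16 measured members had their 2 highest values there. The gap between the score of these libraries and the other 4 was 2.96 on the log2 scale. Mb and Myh2 were the most abundant members. Myh2, a myosin of oxidative and not of slow fibres, was at 3050 CPM in MERKO 1, 1514 CPM in control 1 and 722 CPM in MERKO 3. Genotype does not set these libraries apart, since they belong to different groups, and the group means of the score differed by 0.228. The pattern was picked as high in 1 library of each group, so this restates it and is no test of genotype. Both libraries lay on 1 side of the other 4 in 0 of 3 measures, library size, rRNA share and mitochondrial share. The rule breaks when 1 library is out of order. Library size and mitochondrial share were also taken with the rRNA counts included, which differed widely between libraries. The rule therefore cannot decide against either of them. The rRNA share stays open as well, since control 3 alone broke the order. MERKO 1 and control 1 had 6.19% and 11.1%, against 0.0433% in control 3 and 19.2% to 32.4% in MERKO 2, MERKO 3 and control 2. A larger portion of slow or oxidative muscle in these pieces of quadriceps may account for the pattern. Respiratory chain genes were likewise highest in both, with a gap of 0.372 in the score and 75 of 80 members. Proteins encoded by mitochondrial DNA, with uncertain counts, did not follow, with scores of -0.013 in MERKO 1 and 0.344 in control 1 against 0.435 in MERKO 3. Both libraries carry replicate number 1, and a shared preparation was not tested as a cause. Of the 16 slow-fibre genes, 3 (Casq2, Atp2a2 and Pln) are also in another list.

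Tendon genes were higher and adipocyte genes lower in MERKO, and the difference between both scores was 3.26, 1.56 and 0.167 in MERKO 1 to 3 and -0.00743, -3.58 and -1.40 in control 1 to 3. A lower share of muscle RNA in MERKO would by itself raise markers of both tissues. The adipocyte genes were lower instead, with a mean log2 fold change of -1.71, which argues against that share as the sole cause. A lower share together with less fat is not excluded. The SE over members, 0.23, treats genes that vary together as independent and does not measure the spread between libraries. Uneven amounts of tendon and fat in the dissected pieces stay open. Members of each list varied together between libraries of a group, with estimated correlations of 0.617 for tendon and 0.682 for adipocyte genes. This cannot decide the question, since such correlations are not particular to these lists. They ran from -0.0312 to 0.918 over all lists, with 0.747 for cytosolic ribosomal proteins and 0.663 for macrophages. Genotype stays open, since 3 libraries per group allow no exact permutation p below the 0.1 observed. The most abundant members were Car3 (803 CPM, also made by muscle fibres), Fabp4 (110 CPM) and Cfd (51.7 CPM) for fat, and Thbs4 (62.8 CPM) and Fmod (51.7 CPM) for tendon; 2 members of each list are also in another list.

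Gm15564, an antisense gene model, was at 36.2, 97.5 and 3.42 CPM in MERKO 1 to 3 and between 0.735 and 1.58 CPM in control (called by DESeq2, edgeR adjusted p = 0.631), and Lars2, the mitochondrial leucyl-tRNA synthetase, at 381, 831 and 76.5 CPM against 25.6 to 61.9 CPM, while Gm42418, which overlaps the rRNA model CT010467.1 on the opposite strand, was at 1524, 5293 and 811 CPM in MERKO and between 339 and 774 CPM in control. For Gm15564, carry-over of 18S rRNA is argued against, since MERKO 3, control 1 and control 2, each with a larger CT010467.1 share than MERKO 1, had at most 3.42 CPM. MERKO 2 had the largest share. Lars2 and Gm42418 were not tested in this way, and carry-over of other rRNA was not examined. Gm42418 and CT010467.1 are identical over 1244 bases on opposite strands, so carry-over stays open for Gm42418. Reads of a common origin counted to both Lars2 and Gm15564 may account for the values of MERKO 1 and 2, but this stays open. The genes share a stretch of 72 bases at 98.6% identity. The excess of Lars2 over the control median was 9.84 and 8.25 times that of Gm15564 in MERKO 1 and 2, a 1.19-fold difference. Any factor that raised both genes together could give such similar ratios. The positions of the reads were not examined, so the ratios cannot decide. In MERKO 3, whose excess was small, the ratio was 16.9, and between 7.94 and 19 depending on which control library was subtracted, so the explanation is limited to MERKO 1 and 2. Genotype stays open, with an exact permutation p of 0.1, the smallest that these group sizes allow.

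The 10 splits of the 6 libraries into groups of 3 are too few for a share under 0.05. The real split gave 1 gene and the highest of the others 6, and 2 of 10 splits gave at least 1. At an unadjusted p under 0.05 the real split gave 960 genes and the highest other, with MERKO 1, MERKO 3 and control 1 together, 1475. For the gene lists the real split gave 14 and the highest other split 21, and 5 splits gave at least 14. The 4 splits that placed MERKO 1 and control 1 in the same group gave 21, 21, 19 and 14 lists. This pair was singled out from the same data, and the counts rest on the preset correlation. They are therefore no separate evidence of a structure apart from genotype.

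A hypothesis was that genes close to Esr1 on chromosome 10 differ because the targeted allele may lie in a stretch from another strain. Of 26 genes tested within 5 Mb, Esr1 left out, 1 (Mthfd1l, log2 fold change 0.81, SE 0.26) had an unadjusted p under 0.05, which is 3.85% (upper 95% bound 19.6%) against 7.04% of other genes (exact one-sided hypergeometric test, p = 0.851). The test gave no sign of such a stretch and is too small to exclude it.

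The low values of Fkbp5 and of Trim63, both known to be induced by glucocorticoids, led to the hypothesis of lower glucocorticoid signalling in MERKO. In a list of 28 other responsive genes, 23 were lower (mean log2 fold change -0.14), with a camera p of 0.00416 at the preset correlation and 0.34 at the estimated correlation of 0.294. The hypothesis cannot be told apart from variation between libraries in genes that vary together, and the exact permutation p of the list score was 0.5.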
